A study of Caenorhabditis elegans with 4 samples.

How the data were processed

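ChIP-seq peak lists were analysed for ZIP-2::GFP in C. elegans strain OP432 at the L4 stage, grown at 20 °C. Per the labels' protocols, worms were fixed with 2% formaldehyde, chromatin was sheared by sonication, part of each lysate was kept as input, and the rest was incubated with antibodies to GFP. Per the file headers and columns, binding sites were called with PeakSeq on WormBase WS180. The q-value of each peak was computed by the authors before deposit and is the unit of the score column; the attribute column repeats it in all 1262 rows. The PeakSeq version, the aligner, the q-value limit, the control used and the way the replicates were combined are not given in the sources used here. The lists hold no summits, fold enrichments or read counts, so depth is unknown, and a q-value depends on depth as well as on enrichment. For that reason q-values were used to rank or describe peaks within a list, and a larger number of peaks in a list was not read as more binding.

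The 2 ChIP samples and 2 input samples were grouped by their titles. The titles do not say whether the replicates came from separate cultures, so agreement between them may be technical in part. No sequencing batch or date is given in the labels used here. No file of the input samples was analysed here, so they entered no comparison.

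A peak counted as shared when it overlapped another by at least 1 bp. Overlap of the replicate lists was compared with 10000 random placements within chromosomes. WS180 chromosome lengths were not used here, so each chromosome's span was taken as the highest peak end on it in any of the 3 lists, which is a lower bound of its length. Random placement treats all positions in the span as able to hold a peak and ignores repeats that reads cannot be assigned to. The share of sites per chromosome and in the central 50% of the autosomes (by peak midpoint) was tested with two-sided exact binomial tests. These tests treat peaks as independent, so alternatives merged peaks within 2000 bp of each other or permuted bins of 1 Mb. Correlations used 100000 permutations. The threshold was an adjusted p of 0.05, and exact 95% intervals are Clopper-Pearson intervals. The 10 strongest combined peaks were named by position, under a rule that applied where no gene annotation of the build could be used. Other positions that are named, at the end of chromosome I, on chromosome III and in the densest window, were chosen after their values were seen.

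Alternatives were other overlap rules (50% of the shorter peak, midpoints within 250 bp), stronger sublists, sublists overlapping 1 or both replicates, circular shifts, and the number of protein-coding genes per chromosome as the expected share. The gene table at hand describes WBcel235. Its coordinates were not joined to the peaks, and it was used only for the number of the 19971 protein-coding genes on each chromosome and for the chromosomes of zip-2 and unc-119. The planned comparisons with gene starts, with 19 gene lists and with 13 sequence motifs needed an annotation or a genome of WS180 and were not run.

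The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests of the overlap, the X share, the central share and the correlation were checked on simulated data of the same size. For the overlap and the correlation, the checks used fewer random draws than the main tests. The tests of replicate support by chromosome, of spacing and of permuted bins were not checked in this way. Apart from the planted effects, simulated peaks were drawn independently and evenly along the span, so the checks do not cover peaks that cluster. Copying 20 peaks of replicate 1 into a list of 192 was detected in 100 of 100 simulations, and unrelated lists were called in 1 of 100. A 1.5-fold weight on X in a list of 755 was detected in 99 of 100, and an even spread was called in 3 of 100.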

Results

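Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where ZIP-2 sits on the genome of Caenorhabditis elegans at the fourth larval stage (L4). ZIP-2 is a bZIP transcription factor known for its part in the transcriptional response to Pseudomonas aeruginosa and to blocked translation. The hermaphrodites carried an integrated zip-2 transgene fused to GFP, and chromatin was pulled down with an antibody to GFP. The series held 2 ChIP samples and 2 matched input samples, each numbered replicate 1 and 2. The peak lists analysed here were 1 per ChIP replicate and 1 combined list. Replicate 1 held 315 peaks, replicate 2 held 192 and the combined list held 755. No peak list of an input sample was analysed here, so no background could be measured in the same way. The lists give positions in the WormBase WS180 genome and the authors' q-value for each peak, with no gene names and no read counts. Sequencing depth is therefore unknown, and every interval given here covers the counting of peaks only.

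Peaks of all 3 lists were short. The median width was 618 bp in replicate 1 (interquartile range 405.5 to 888 bp), 633.5 bp in replicate 2 (400.5 to 846 bp) and 596 bp in the combined list (418 to 954.5 bp). The peaks covered 232.0 kb in replicate 1, 137.2 kb in replicate 2 and 600.8 kb in the combined list, or 0.603% of the 99.6 Mb spanned by the lists. The weakest peak kept had a q-value of 5.56e-05 in replicate 1, 4.53e-05 in replicate 2 and 9.6e-05 in the combined list.

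The first comparison asked which binding sites were found in both replicate ChIP samples. Of the 192 peaks of replicate 2, 157 (81.8%) overlapped a replicate 1 peak by at least 1 bp. In the other direction, 158 of the 315 replicate 1 peaks (50.2%) overlapped a replicate 2 peak. When the replicate 2 peaks were placed at random along their own chromosomes, 1.08 of them overlapped replicate 1 on average, and at most 7 did in 10000 placements (one-sided permutation of positions, p = 1e-04, the smallest that number of placements can give). The strongest sites were nearly all shared. All 50 of the strongest peaks of replicate 2 had a partner in replicate 1, and 49 of the 50 strongest of replicate 1 had one in replicate 2. Peaks without a partner were weaker: their median −log10 q-value was 5.40, against 10.8 for shared peaks in replicate 1, and 4.90 against 7.51 in replicate 2 (two-sided permutation test of ranks within each list, p = 1e-05 in both, the smallest that 100000 permutations can give). The exception among the strongest sites was the top peak of replicate 1, at chromosome I 15063998 to 15067651, which overlapped no peak of either other list (−log10 q = 246). The next replicate 1 peak without a partner ranked 73rd (−log10 q = 12.5).

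The order of the shared sites by strength was also similar in the replicates. Over the 150 one-to-one pairs of overlapping peaks, Pearson's r between the log10-transformed −log10 q-values was 0.89 and Spearman's rho was 0.79 (two-sided permutation p = 1e-05 for each, the smallest possible). Without the 2 peaks farthest from the median, r was 0.88. This is a correlation across peaks, which are not independent replicates, and peaks below the q-value limit of either list are missing from it.

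**Figure D1:**
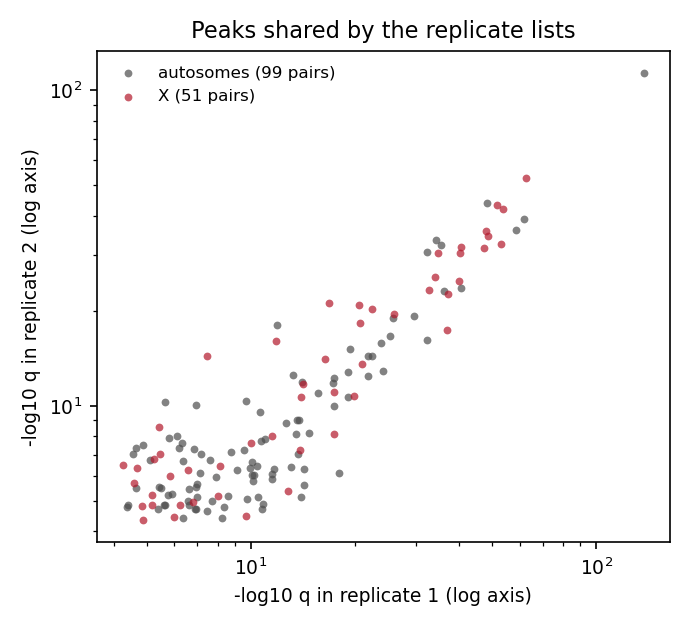
Strength of the 150 peak pairs shared by the replicate lists, as −log10 q-value in replicate 1 (x, log axis) against replicate 2 (y, log axis); each point is a pair, with 99 pairs on autosomes in grey and 51 on chromosome X in red. Spearman's rho across the pairs was 0.79.

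The second comparison gave the replicate support behind the combined list. Of its 755 sites, 153 (20.3%) overlapped peaks of both replicates, 140 overlapped replicate 1 only, 31 overlapped replicate 2 only and 431 (57.1%) overlapped neither. Support fell steeply with strength. In the strongest 151 sites, 118 (78.1%) were in both replicate lists and 4 were in neither, while in the weakest 151 sites 0 were in both and 143 (94.7%) were in neither. Sites in both lists had a median −log10 q-value of 19.9 and a median width of 831 bp, against 5.20 and 516 bp for sites in neither list. The combined list was made from the same samples, so no test was applied to these counts. Nearly all replicate peaks were kept in it, with 303 of 315 from replicate 1 and 190 of 192 from replicate 2.

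**Figure D2:**
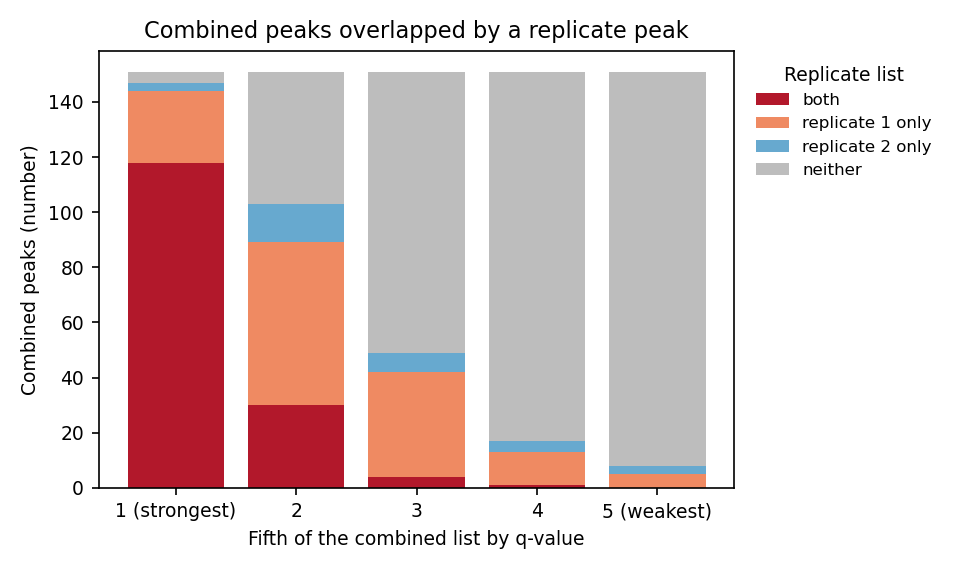
Number of combined peaks (y) in 5 groups of 151 peaks ordered by q-value (x, strongest at the left), coloured by the replicate lists that hold an overlapping peak. Peaks in both lists make up 118 of the strongest 151 and 0 of the weakest 151.

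The 10 strongest combined sites, named by a rule set before the data were examined, were divided equally between chromosomes V and X, and each was present in both replicate lists. The strongest lay at chromosome V 4041037 to 4043607 (−log10 q = 211), followed by chromosome X 14476325 to 14477850 (98.2) and chromosome X 14525322 to 14526336 (93.2). The next were chromosome V 122720 to 124315 (90.8), chromosome X 8035832 to 8036894 (85.95), chromosome X 2996289 to 2997534 (85.2) and chromosome V 16394930 to 16395550 (84.2). The list was completed by chromosome X 1453744 to 1455114 (80.4), chromosome V 723599 to 728647 (77.7) and chromosome V 5080648 to 5081544 (77.5). Of the 20 strongest sites, 12 were on X and 6 on V, and all 20 were in both replicate lists. The gene beside each site is not given here, because the gene table at hand describes a later genome build.

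The third comparison asked how the sites were spread over the 6 nuclear chromosomes. Chromosome X held more sites than its size predicts, and chromosome I held fewer. X carried 177 of the 755 combined sites (23.4%, exact 95% binomial interval 20.5 to 26.6%) against 17.6% of the span, or 10.1 sites per Mb (two-sided exact binomial test, Benjamini-Hochberg adjusted over 6 chromosomes, p = 0.000345). Chromosome I carried 85 sites (11.26%, 9.09 to 13.7%) against 15.1% of the span, or 5.64 sites per Mb (adjusted p = 0.0069, same exact test). Chromosomes II, III, IV and V held 121, 86, 123 and 163 sites, between 0.832 and 1.05 times the number that an even spread predicts, and none passed the test (adjusted p from 0.143 to 0.655, same exact test). Chromosome III passed among sites with replicate support, with 10 of the 153 found in both replicate lists (6.54% against 13.7% of the span, adjusted p = 0.0182, same exact test). It did not in the stronger 50% of the combined list, where 50 of 377 sites were on III (13.26%, adjusted p = 1, same exact test).

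The contrast between X and I was larger among sites found in both replicates. Of these 153 sites, 52 (34.0%, 26.5 to 42.1%) were on X and 6 (3.92%, 1.45 to 8.34%) were on I. Sites on X were found in both replicate lists more often than autosomal sites, at 52 of 177 (29.4%) against 17.5% of 578 (odds ratio 1.96, two-sided Fisher's exact test, adjusted over the 6 chromosomes p = 0.00263). Permuting support within groups of 15 sites of consecutive rank gave 42.1 such sites on X on average against the 52 observed (two-sided permutation test, adjusted p = 0.00126), and within the 5 groups of 151 sites, which match strength only coarsely, 38.1. Sites on chromosome I were found in both lists less often than sites elsewhere, at 6 of 85 (7.06%) against 147 of 670 (21.9%; odds ratio 0.27, Fisher's exact test, adjusted over the 6 chromosomes p = 0.00263). Permuted within groups of 15 ranks, 12.5 such sites were expected on I against the 6 observed (permutation test, adjusted p = 0.0033). On chromosome III, 10 of 86 sites were in both lists, which missed the threshold in the Fisher test (adjusted p = 0.0659, exact) and passed it within groups of 15 ranks (16.7 expected; permutation test, adjusted p = 0.00568). These tests of support by chromosome were added after the lists had been examined.

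**Figure D3:**
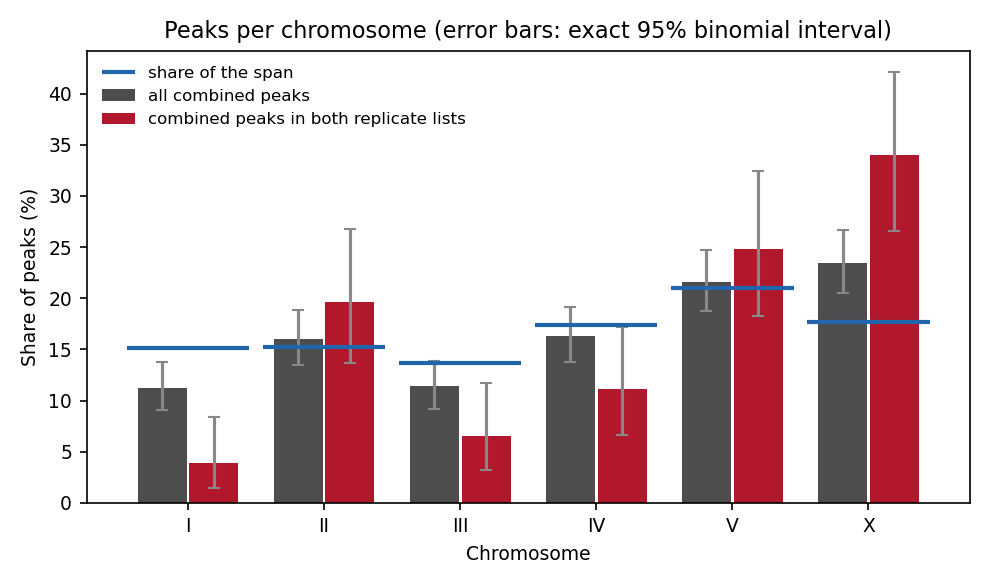
Share of peaks (y, %) on each chromosome (x) for all 755 combined peaks (grey) and the 153 found in both replicate lists (red), with exact 95% binomial intervals as error bars and the chromosome's share of the span as a blue line. X lies above the line in both sets, at 23.4% and 34.0%, and I lies below it, at 11.26% and 3.92%.

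The fourth comparison set the centres of the autosomes, which hold more conserved genes than the arms, against their outer parts. The central 50% of the 5 autosomes held 346 of 578 combined sites (59.9%, exact 95% binomial interval 55.7 to 63.9%; two-sided exact binomial test against 50%, p = 2.42e-06). Chromosome I had 64.7% of its sites in the central 50%, chromosome III 63.95% and chromosome V 61.3%, and these 3 passed the test after adjustment over 6 chromosomes (adjusted p = 0.0253 for each, same exact test). On chromosome X, 87 of 177 sites lay in the central 50% (49.2%, 41.6 to 56.8%; adjusted p = 0.881, same exact test). The excess was not detectable among the autosomal sites in both replicate lists, of which 51 lay in the central 50% (50.5%, 40.4 to 60.6%; p = 1, same exact test). It also missed the threshold among sites overlapping replicate 1 (56.7%, p = 0.0622), among those overlapping replicate 2 (51.6%, p = 0.786) and in the stronger 50% of the list (54.5%, p = 0.139; same exact test). A direct comparison of sites in neither list (62.0% of 347) with sites in at least 1 (56.7% of 231) did not find a difference (odds ratio 1.24, Fisher's exact test, p = 0.226). It grouped sites in 1 list with sites in both. Sites in both lists (50.5%) and the stronger 50% (54.5%) had lower central shares than all autosomal sites (59.9%), so the remaining sites had higher ones. Sites in both lists were not tested directly against the rest, nor was the stronger 50% against the weaker 50%. Whether these differences exceed chance therefore stays open.

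**Figure D4:**
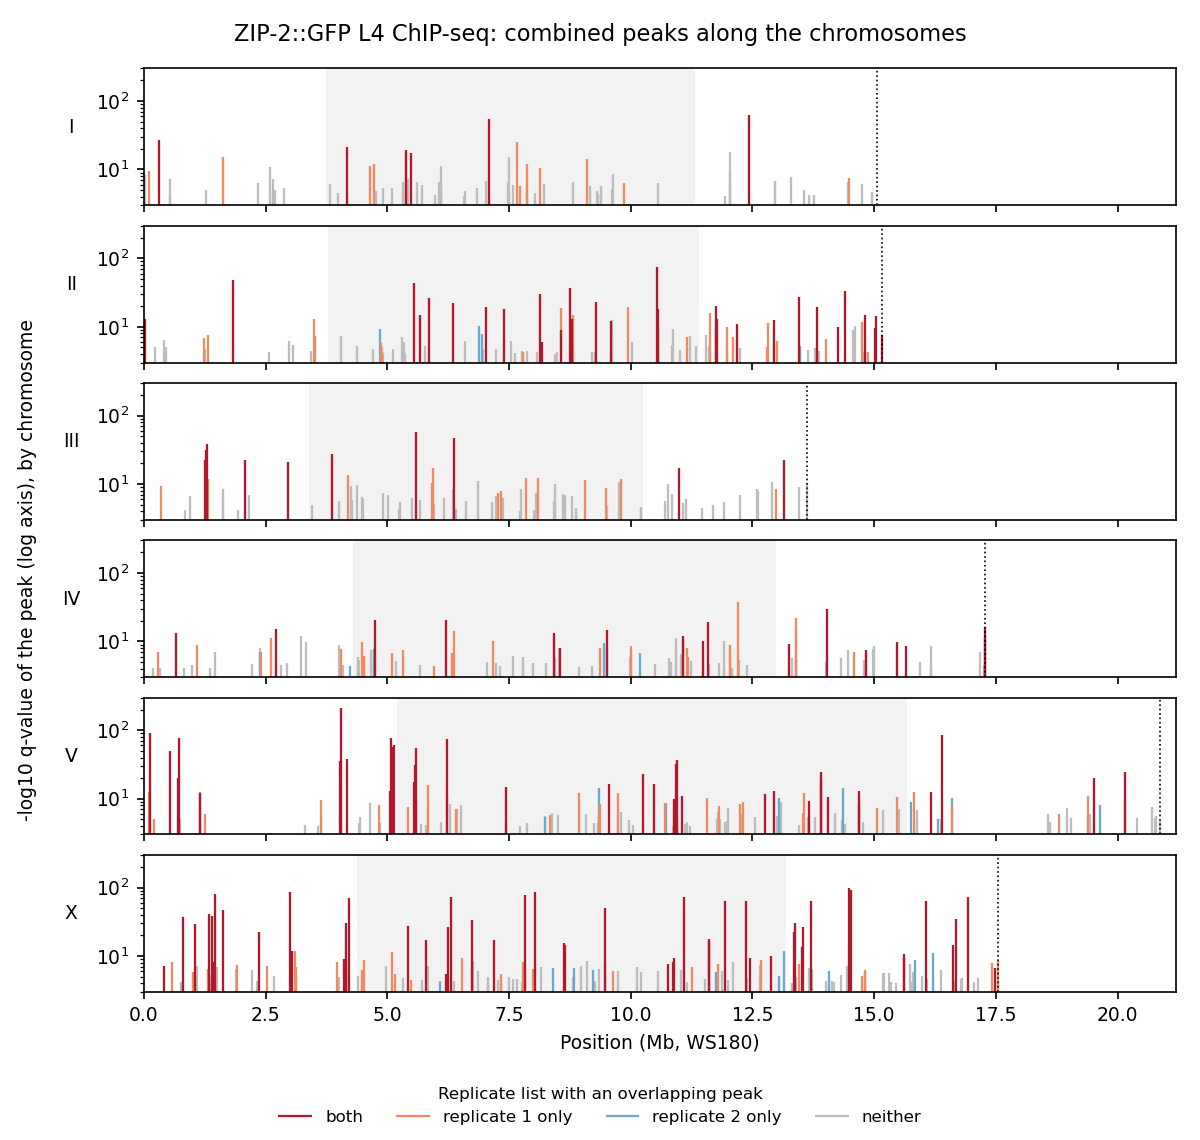
Position of each combined peak (x, Mb in WS180) with its strength as −log10 q-value (y, log axis) on the 6 chromosomes, coloured by the replicate lists that hold an overlapping peak. Grey shading marks the central 50% of each span and the dotted line its end; of the 20 strongest peaks, 12 stand on X and 6 on V.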

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

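The overlap of the replicate lists, the correlation of strengths, the X excess and the chromosome I deficit kept their direction and their side of the threshold under each alternative run for them. The share of sites on X ranged from 23.4% to 34.0%, and that on I from 3.26% to 11.28%. The X excess also held against the share of protein-coding genes (13.7% on X), with peaks within 2000 bp merged (23.9%) and with 1 Mb bins permuted; these 3 alternatives, the circular shift, and the tests of replicate support by position were chosen after seeing the data. The excess in the central 50% of the autosomes depended on the peak set, as did the call on chromosome III. The central share was 50.5% in sites of both replicate lists and 54.5% in the stronger 50% of the combined list, and from 51.6% to 56.7% with 1 replicate required, all short of the threshold; these sets are smaller, and the cause was not tested. The excess held with the central 33.3% of each span (41.9%), with peaks merged (60.2%) and with bins permuted (62.9%). Restricting each list to its stronger 50% left 80 of 96 replicate 2 peaks shared and 79 combined peaks in both lists, since fewer peaks entered. On chromosome II the share, never past the threshold, fell below expectation in the stronger 50% (15.1%) and against gene number (16.03%). On chromosome III the share passed the threshold in sites of both replicate lists (6.54%) and with 1 replicate required (5.43% to 7.85%), and not in the stronger 50% (13.26%). With replicate support permuted within groups of 15 or 151 ranks, the excess of support on X and deficit on I held, that on III passed the threshold only there, and support on V turned to 0.963 times the expected number with 151, never past the threshold. On chromosome V the share of sites fell below expectation against gene number (21.6%) and with peaks merged (20.6%), again short of the threshold. Leaving out a replicate was not possible for the overlap and the correlation, which need both. No paired analysis was possible because no file of the input samples was used here and each ChIP replicate has a single list. No second strength measure was in the lists. Depth is unknown, so a site missing from a replicate list was not detected there at the authors' limit and is not shown to be unbound.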

Other observations

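The called peaks of the combined list lay closer together than a random spread gives. In 81 of 749 cases the gap to the next site on the chromosome was at most 2000 bp, against 16.102 on average and 30 at most in 1000 random placements (one-sided permutation of positions, p = 1e-03, the smallest possible). Among sites in both replicate lists, 7 of 147 gaps were that short, against 0.94 on average. The count cannot separate distinct binding sites from 1 enriched region called as several peaks. Of 24 combined sites above 2000 bp (all but the widest), 9 overlapped 2 or more peaks of the same replicate list. The densest 100 kb window of the combined list was on chromosome V, where 8 sites lay between 10859311 and 10954115. Widths above 2000 bp were seen in 25 combined sites, 14 of which were in both replicate lists. The tests in this part were chosen after the lists had been examined; the X share in the stronger 50% of the list had been planned as an alternative, but its use here had not.

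The strongest peak of replicate 1, at the right end of the chromosome I span, was in neither other list, although its −log10 q-value was 1.80 times that of the next peak. A generally lower sensitivity of replicate 2 for strong peaks is argued against by the next 49 strongest peaks of replicate 1, of which 49 had a replicate 2 partner. The other 11 replicate 1 peaks missing from the combined list were weak, with −log10 q-values of at most 5.49. The combined list may leave out this end of the chromosome: it held 0 peaks in the last 100 kb of the span, but an even spread would put only 0.564 there, so this cannot be told apart from chance. The ribosomal DNA repeats lie at this end of the chromosome, and a difference in repeat reads between ChIP and input of replicate 1 stays open, as does real binding; neither was tested.

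The excess of sites on X was weighed against 3 explanations. It was not limited to peaks near the calling threshold, since the lower 95% bound of the X share was 19.9% in the stronger 50% of the list, above the 17.6% of the span. A few clusters of neighbouring peaks are argued against by 1 Mb bins. These held 10.1 ± 3.40 sites on X (SD, 17 bins) and 7.01 ± 3.73 on autosomes (SD, 80 bins, two-sided permutation p = 0.0024). Autosomal bins were not alike, with 8.61 ± 3.47 sites in the central 50% (SD, 41 bins) and 5.33 ± 3.26 outside it (SD, 39 bins). X was not tested against the central bins alone. Gene number would give fewer sites on X, which holds 13.7% of protein-coding genes but 17.6% of the span. The lower bound of 20.5% for all sites, already above the share of the span, had to lie above the gene share too. It is therefore no separate test. A scaling of ChIP to input that differs between chromosomes, mappability and accessible chromatin in the L4 worm stay open and were not tested, and the design has no group that would test a biological explanation.

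The widest combined site, 12760 bp at chromosome III 831505 to 844264, ranked 725th of 755 and overlapped no replicate peak. The other 24 sites above 2000 bp had −log10 q-values of at least 7.31, and 21 of them overlapped a replicate peak. A low and broad signal could come from extra copies of sequence around an integrated transgene, and zip-2 and unc-119, the 2 genes named in the transgene, both lie on chromosome III. Input from the same lysates would hold the same copies, and whether it was the control is not given. With a −log10 q-value of 4.11 and no WS180 position for either gene used here, the transgene explanation stays a hypothesis that the lists cannot decide. A merger of neighbouring sites was not tested and also stays open.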
